A study of Xenopus tropicalis with 24 samples.

How the data were processed

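The series compared transcript levels in Xenopus tropicalis, the western clawed frog, after exposure to 1 of 3 phthalates, each with its own control group. The phthalates were dicyclohexyl phthalate (DCHP) and dimethyl phthalate (DMP), which are diesters of phthalic acid, and monomethyl phthalate (MMP), the monoester that corresponds to DMP. There were 24 arrays in 6 groups of 4. The labels give eggs as the source and as the stage, and state neither doses nor exposure times, so doses may differ between the compounds. They do not say whether the 4 samples of a group came from separate clutches, tanks or animals, so p-values measure only the spread between these samples, which may be partly technical. A rise or fall with a compound below is a difference between its group and its control group, which may also differ in origin. Groups were taken from the agent label of each sample, and replicate numbers from the sample titles. The titles also carry codes that the labels do not define: LM for DCHP, MH for DMP and XH for MMP. The DCHP control carries SC, and the MMP and DMP controls carry C. Whether the exposures, or the controls, were of one kind therefore cannot be told.

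Total RNA was labelled with Cy3 and hybridised to a one-colour Agilent oligonucleotide array, per the labels' protocols. The arrays were scanned and read with Agilent Feature Extraction 10.7.1.1, per the file headers. The intensity values used were the processed signals in the deposited scanner files, which Feature Extraction had background-subtracted and spatially detrended within each array, per the file headers, with no normalization between arrays. The deposited series matrix held log2 values that the authors had normalized. From the values, all 24 of its columns had medians of 6.91 to 6.92, 14.1% of its values lay at a floor of 2.7, and each column correlated best with the scanner file of its own array, with r of 0.991 or higher. It was used as an alternative only.

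Each array held 45220 spots, of which 1417 were control spots and were left out. The remaining 43803 spots read 32899 probes, 10904 of them spotted on 2 positions. Log2 of the processed signal minus the array's 75th percentile was taken, spots marked as outliers by the scanner software (0 to 61 per array) were set to missing, and spots of one probe were averaged. A probe was tested if it was well above background on at least 4 of the 24 arrays, which left 27808 probes. At most 1 spot per array was saturated. Between 67.1% and 84.8% of spots were well above background per array, and the number of arrays, 4 per group, limits the precision.

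Probe accessions were named through a RefSeq gene table of assembly UCB_Xtro_10.0, without versions on both sides. Of the probes, 5891 matched a symbol, 27008 did not and none matched several, and no coordinates were used because the array was designed on an older assembly. Symbols that are locus or clone numbers were not used, which left 4221 named genes among the tested probes. A gene was read through its tested probe with the highest mean signal. Probe names carry a class: 12889 of the tested probes were of a class whose name points to cross-hybridization and 14919 of a class named specific, and 987 named genes were read through a probe of the first class. The files do not define the classes. Besides the probes marked so in the results, vegfd, abraxas1, ces3.4, ush1c, prr15 and ndufs4 were read through the first class. So were c12orf73, b4galt3l2, glyatl2, dus1l, ncs1 and pxdn. The tested probes include 437 repeat probes, in 48 sets of up to 10, each set reading a single transcript, and these were counted separately.

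All 24 arrays were fitted in one model of 6 group means with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 18 residual degrees of freedom. Each compound was compared with its own control, and the effects of each pair of compounds were compared by the difference of these differences. Tests were two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Every adjusted p of a gene is from limma. Where a probe was not well above background on any array of a group, its fold is a lower bound: the mean of the brighter group against the mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background. Intervals of differences are 95% intervals, from the limma fit for genes and from the spread of per-array means for gene lists.

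Before the data were examined, 34 gene lists were fixed, 18 of pathways and 16 of cell types or stages, together with the tests, the alternatives and the rule for named genes. Lists with at least 5 tested genes, 26 in all, were tested with limma's camera at its preset correlation of 0.01, with adjustment over all lists within a comparison. Camera compares a list with all other genes, so it can miss a list whose own mean lies away from 0. The 8 lists with too few tested genes were xenobiotic conjugation and export (4 tested genes), cytosolic ribosomal proteins (2), egg and germ line (4), blastula and gastrula (2), hatching and cement gland (2), heart (3), red blood cell (4) and pigment cell (4). In 31 of the 78 list results of the 3 comparisons the mean, the median and the direction of the test differed in sign, and none of these passed. Named genes were, for each comparison with control, the 10 largest rises and 10 largest falls past the threshold, up to 4 members of each list that passed, and, for each difference between compounds, the 5 genes with the smallest p. A further 7 genes of phthalate and hormone action were to be named whatever their p, of which ar and ppara had a tested probe. cyp1a1, thrb, srd5a1, srd5a2 and esr1 had none with that symbol. Other members of lists, and the genes that passed in all 3 comparisons, were named outside this rule, after their values had been seen.

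The alternatives were normexp background correction with an offset of 50, quantile normalization, the authors' matrix values, no filter and a stricter filter on dim probes, keeping the spots marked as outliers, slide as a fixed or random block, array weights, a variance trend with robust estimation, only the arrays of the compounds compared, other thresholds, other list tests, and leaving out each replicate in turn. Scan day (slides 1 and 2 on one day, slides 3 to 6 on another), a fixed block for it and, for the lists, leaving out genes read through probes of the cross-hybridizing class were added after the data had been seen. The files do not hold mean spot signals, so normexp used median signals. A first run of it, on all local backgrounds as measured, at least doubled the corrected median of 6 arrays, by up to 13.9 times, and gave counts far from every other setting. It was therefore repaired after its outcome had been seen, by giving spots marked as background outliers (67 to 1844 per array) the median background of their array.

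The steps were tested on simulated data. For the DCHP comparison, over 27808 probes, 44.0% of 50 probes changed by 0.5 on the log2 scale were recovered, 90.0% of those changed by 1, 98.0% of those changed by 2 and all 50 changed by 3, with 7 false calls. The simulation changed far fewer probes than passed with DCHP in the data (3828) and drew independent normal noise, without slide or scan day. These shares and false calls therefore describe the simulated arrays, not the real comparison. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.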

Results

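Transcript levels were measured on 24 one-colour arrays of Xenopus tropicalis RNA, in 6 groups of 4: samples exposed to DCHP, MMP or DMP, and a separate control group for each phthalate. The series title gives the aim as the effects of phthalates on development of this frog. The 24 arrays lay on 6 slides of 4. Each slide held several groups, and each compound shared 3 slides with its own control. The 75th percentile of the processed signal ranged from 188.4 to 445.2 on the 8 arrays of slides 1 and 2, which were scanned on one day, and from 553.8 to 1216.6 on the 16 arrays of slides 3 to 6, scanned on another. Replicate arrays correlated with Pearson's r of 0.975 to 0.993 across probes within groups.

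The labels give eggs as the source, but genes of differentiated tissues were well above background. Of the named genes on the array, 10 of 10 liver genes, 8 of 8 skeletal muscle genes, 15 of 16 eye and lens genes and 10 of 11 neuron and brain genes were detected on at least 4 arrays. By the same rule 4221 of all 4634 named genes were detected, so these high shares do not set the tissues apart from other genes. The lowest shares were 2 of 7 blastula and gastrula genes, 4 of 10 egg and germ line genes, 4 of 7 red blood cell genes, 2 of 3 hatching and cement gland genes, 5 of 7 immune cell genes, 9 of 12 gut and pancreas genes and 3 of 4 heart genes.

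DCHP raised cyp2c19, por and c5, among others, and lowered tnnt1 and pvalb. The largest rise among named genes was in arsa.2, a gene for the lysosomal enzyme arylsulfatase A, at 1.23 ± 0.40 on the normalized log2 scale against -1.85 ± 0.16 in its control (SD, n = 4), an 8.45-fold increase (adjusted p = 7.73e-10). Probes named for the cytochrome P450 genes cyp2a13l and cyp2f1 rose 7.28-fold and 7.02-fold (log2 2.86 and 2.81, each with a standard error of 0.13). The largest fall among named genes with signal in both groups was in tnnt1, which encodes slow skeletal troponin T and was lower by 3.74-fold (log2 -1.90, standard error 0.20, adjusted p = 9.91e-07).

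In all, 3828 of 27808 probes passed adjusted p 0.05 with DCHP, 1962 higher and 1866 lower, and 660 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 7269 probes, where chance alone gives 1390. Among 4221 named genes, 288 rose and 293 fell. The other rises among the 10 largest of named genes were in rbm48 (log2 2.84), pinopsin100496420, named for a photopigment of the pineal organ (2.09), fosl1, a component of the AP-1 transcription factor (2.07), adm2, which encodes the peptide hormone adrenomedullin 2 (1.94), and trmt12, a tRNA-modifying enzyme (1.90). The complex I subunit ndufs1 and the mediator subunit med20 were not well above background in the control and rose at least 3.23-fold and 2.94-fold (adjusted p = 0.000304 and 0.0175). The probes of ndufs1, med20, fosl1 and trmt12 belong to the cross-hybridizing class, as do those of cyp2a13l, cyp2f1 and rbm48, whose signals tracked one another over the 24 arrays with r of at least 0.9986, so they were not separate measurements. The fosl1 rise had a within-group SD of 2.25 in DCHP, the groups overlapped, and its adjusted p of 0.037 became 0.0644 with slide as a fixed block and 0.103 with array weights, and it did not pass without 5 of 8 single replicates (log2 1.39 to 2.76).

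Among the falls, the keratin gene krt78.1 was 3.14-fold lower (log2 -1.65, adjusted p = 6e-07), the ATPase gene atp13a-like changed by -1.87, the meiotic recombination gene hsf2bp by -1.64, the glutamate transporter gene slc1a1 by -1.59, the lymphatic growth factor gene vegfd by -1.45 and the DNA repair gene abraxas1 by -1.40. In nectin1l2.2, named for a cell adhesion protein, the DCHP arrays were not well above background and the fall was at least 5-fold (log2 -3.12, adjusted p = 0.00263), with overlapping groups, a control SD of 2.04 and log2 values of -4.07 to -2.52 without single replicates. It was at least 2.15-fold in krt78.2 and at least 2-fold in klhl14. Fitted on the DCHP arrays and their controls alone, nectin1l2.2 and med20 did not pass (adjusted p = 0.063 and 0.081). The med20 call held in 6 of 8 fits without a single replicate (log2 1.29 to 2.25). With normexp background correction 15 of the 34 genes chosen by the rule set beforehand that had passed with DCHP did not pass. Among them were nectin1l2.2, krt78.2, klhl14, med20, trmt12 (log2 0.36, adjusted p = 0.589) and mbl2 (0.20, adjusted p = 0.683).

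Of the 10 tested genes of xenobiotic phase I metabolism, 5 rose and none fell (6 rose when adjusted over the list alone), with a list mean of 0.46 (95% interval 0.36 to 0.57; camera adjusted p = 0.0043, and adjusted p = 0.0286 with an estimated correlation). They were cyp2c19 (log2 1.48, standard error 0.26), ces3.4 (0.96), cyp3a4.2 (0.81), por (0.65) and cyp4v2.1 (0.42), of which ces3.4 gave -0.01 with normexp background correction (adjusted p = 0.984) and cyp4v2.1 passed in 4 of 8 fits without a single replicate. por encodes the reductase that passes electrons to microsomal cytochromes P450, and ces3.4 is named for a carboxylesterase. ahr and nr1i2, receptors that respond to foreign compounds, gave -0.20 and -0.42 and did not pass (adjusted p = 0.433 and 0.566). Limited to probes well above background on all arrays, the list no longer passed (mean 0.20, adjusted p = 0.128), while with normexp it passed with a mean of 0.19 (adjusted p = 0.0126).

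Of the 15 tested genes of innate immunity and complement, 5 rose and none fell (6 rose when adjusted over the list alone), with a mean of 0.40 (95% interval 0.23 to 0.57; adjusted p = 0.0043, and adjusted p = 0.0663 with an estimated correlation). They were mbl2, mannose-binding lectin (log2 1.46), the complement components c5 (0.79) and c8b (0.59), ifih1, a sensor of double-stranded RNA (0.48), and nfkb1 (0.44). il1b gave 1.40 with a standard error of 0.48 and did not pass (adjusted p = 0.0591). This list also did not pass with the stricter filter on dim probes (adjusted p = 0.0796) or with normexp background correction (mean 0.08, adjusted p = 0.145).

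Of the 8 tested skeletal muscle genes, 5 fell and none rose, also when adjusted over the list alone, with a mean of -0.53 (95% interval -0.64 to -0.42; adjusted p = 0.0183, and adjusted p = 0.0663 with an estimated correlation). After tnnt1 came the calcium-binding protein gene pvalb (log2 -1.04), klhl31 (-0.79), neb, which encodes nebulin of the thin filament (-0.34), and the desmin gene des.2 (-0.33), while tcap gave 0.29, ryr1 0.03 and xirp1 -0.18, none of which passed. The neb call was kept in 6 of 14 other settings and without 2 of 8 single replicates, and the klhl31 call in 11 of 14 and 6 of 8. Of 5 tested immune cell genes, 2 rose (3 when adjusted over the list alone): the neutrophil enzyme gene mpo (1.15) and the signalling adaptor gene tyrobp (1.22). il2rg gave 0.48 (adjusted p = 0.0661). The immune cell list had a mean of 0.65 (95% interval 0.33 to 0.96; adjusted p = 0.0326, and adjusted p = 0.302 with an estimated correlation). Within the 3 slides that held both groups, the mean shift was 0.48, 0.39 and 0.46 for phase I metabolism, 0.33, 0.45 and 0.26 for innate immunity, -0.60, -0.48 and -0.57 for skeletal muscle, and 0.16, 0.80 and 0.74 for immune cells. With slide as a fixed block the skeletal muscle and immune cell lists no longer passed (means -0.52 and 0.59, both adjusted p = 0.0556), the muscle mean having moved from -0.53 (standard error 0.052, 18 residual degrees of freedom) to -0.52 (0.059, 13). The immune cell list also failed without DCHP replicate 5, DCHP_control replicate 6 or DCHP_control replicate 2 (adjusted p = 0.0679, 0.0624 and 0.0916). In 2 of the 35 splits of the 8 arrays, the real split included, at least as many lists passed. No other list passed with DCHP in limma's camera test. The liver list had a mean of 0.17 (95% interval 0.06 to 0.27), and its adjusted p was 0.243 in camera and 0.0308 in limma's fry.

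**Figure D1:**
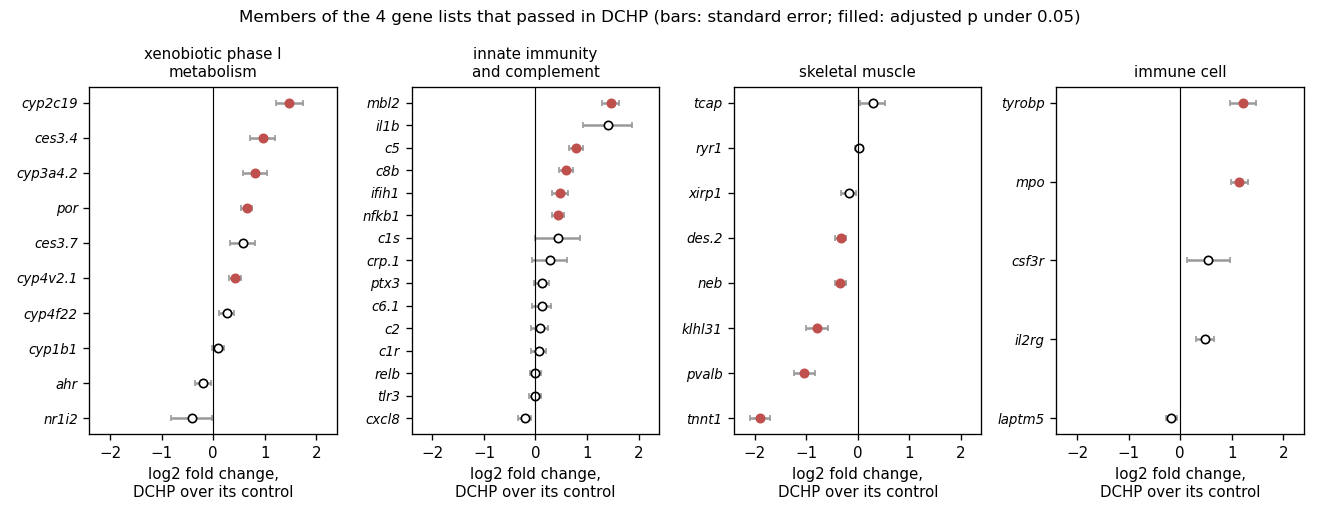
Log2 fold change of DCHP over its control (x axis) for each tested member of the 4 gene lists that passed, with bars for the standard error and filled points for adjusted p under 0.05. In the phase I metabolism panel cyp2c19 lies farthest right at 1.48, and in the skeletal muscle panel tnnt1 lies farthest left at -1.90 while ryr1 and tcap lie near 0.03 and 0.29.

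The androgen receptor gene ar was lower with DCHP by 1.42-fold (log2 -0.51, standard error 0.15, adjusted p = 0.0225), a call that ended in 7 of 13 other settings, among them quantile normalization (adjusted p = 0.0543) and the DCHP arrays and their controls alone (0.11), and without 3 of 8 single replicates. The receptor gene ppara gave 0.08 (standard error 0.25, adjusted p = 0.896). The DCHP count was 4202 probes with slide as a fixed block. It was 1792 with normexp background correction, 2540 on the DCHP arrays and their controls alone, 1953 on scan day 1 alone (2 arrays against 2, with 63.5% of calls higher in place of 51.3%) and 114 on scan day 2 alone (2 against 2).

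MMP changed 394 probes at least 2-fold, and its largest change among named genes was in a gene whose control group stood apart. tnfaip6, which encodes a hyaluronan-binding protein induced by inflammation, was 11.1-fold higher with MMP (log2 3.48, standard error 0.20, adjusted p = 7.87e-10), at 2.69 ± 0.33 against -0.79 ± 0.22 (SD, n = 4). The other control groups lay at 2.57 ± 0.26 (DCHP_control) and 2.71 ± 0.22 (DMP_control), so the MMP samples were at the level of those and the MMP control was below it. The largest fall among named genes was in glyatl2, named for a glycine acyltransferase, which was not well above background on any MMP array and fell at least 5.18-fold (adjusted p = 0.000553). krt78.1 fell here too (log2 -1.36, adjusted p = 4.8e-05).

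With MMP 2768 probes changed, 1493 higher and 1275 lower, of which 394 changed at least 2-fold, and 7341 passed an unadjusted p under 0.05. Among named genes 222 rose and 173 fell. The other large rises were in the RNA helicase gene dhx37 (log2 1.70), b4galt3l2 (1.51, adjusted p = 0.0461) and the netrin-G gene ntng2 (1.5), both with overlapping groups, upf3a of nonsense-mediated decay (1.38), the ribosome assembly gene nop14 (1.37) and the axonemal dynein gene dnai2 (1.33). Without a single replicate the call held in 8 of 8 fits for dhx37 and 6 for ntng2. It held in 4 for nop14, 3 each for upf3a and dnai2, and 2 for b4galt3l2. ntng2, upf3a and nop14 were each well above background on 1 of 4 control arrays, and none of them passed with normexp background correction. The 13 other probes of dnai2 gave -0.11 to 0.24, so its rise rests on a single probe. c12orf73, wdr60, which encodes a ciliary dynein chain, and thsd7b were not well above background in the control and rose at least 2.41-fold, 2.31-fold and 1.43-fold, the last with signal on 1 MMP array. The thsd7b call held in 3 of 8 fits without a single replicate. wdr60 gave -0.03 with normexp background correction, with which 12 of the 20 genes chosen by the rule that had passed with MMP did not pass. Falls were found in pinopsin100496420 (-1.59), cd36l (-1.41), the hormone gene ghrh (-1.17), dus1l (-1.04, adjusted p = 0.0492, groups overlapping), xilr2 (-1.03), the calcium sensor gene ncs1 (-0.95), the aminopeptidase gene enpep (-0.91) and the peroxidasin gene pxdn (-0.91). Without a single replicate the call held in 1 of 8 fits for dus1l and in 3 each for ghrh and pxdn. It held in all 8 for pinopsin100496420, cd36l, xilr2, ncs1 and enpep.

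None of the 26 lists passed with MMP in limma's camera test. The smallest adjusted p was 0.344, for innate immunity and complement (mean -0.14, 95% interval -0.30 to 0.03), where 1 of 15 genes rose and 2 fell. At an unadjusted p under 0.05, 2 lists passed camera, the other being cholesterol and fatty acid synthesis, in which 4 of 12 genes rose (4 when adjusted over the list alone; adjusted p = 0.426). Neither ar (log2 -0.22, adjusted p = 0.341) nor ppara (0.16, adjusted p = 0.72) passed. The MMP count was 3825 with slide as a fixed block. It was 706 with normexp, 1520 on the MMP arrays and their controls alone, 3684 on scan day 1 alone, 2 on scan day 2 alone (1 array against 2), 6172 with array weights, 4431 with slide as a random block and as low as 936, without MMP_control replicate 9, when single replicates were left out. The share of calls that were higher, 53.9%, was 63.2% on the MMP arrays and their controls alone, 48.1% with the authors' matrix and 44.1% without MMP_control replicate 9.

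DMP raised ucp3 and the probes of the cytochrome P450 genes, and lowered krt78.1 and tnnt1. ucp3, which encodes a mitochondrial uncoupling protein, was 7.43-fold higher (log2 2.89, standard error 0.27, adjusted p = 4.7e-07), at 1.27 ± 0.56 against -1.62 ± 0.10 (SD, n = 4). abhd15, named for an alpha/beta hydrolase, was 7.86-fold higher (log2 2.97, adjusted p = 7.34e-06), with signal on 1 of 4 control arrays, and gave 0.50 with normexp (adjusted p = 0.393), with which 9 of the 20 genes chosen by the rule that had passed with DMP did not pass. The probes of cyp2a13l, cyp2f1 and rbm48 rose by 1.70, 1.74 and 1.74. The keratin gene krt78.1 was 4.41-fold lower (log2 -2.14, adjusted p = 2.37e-08) and tnnt1 2.32-fold lower (log2 -1.22, adjusted p = 0.000477).

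With DMP 3326 probes changed, 1577 higher and 1749 lower, of which 445 changed at least 2-fold, and 7318 passed an unadjusted p under 0.05. Among named genes 246 rose and 217 fell. The other large rises were in ush1c, which encodes harmonin (log2 2.19), and erp27 of the endoplasmic reticulum (2.02, adjusted p = 0.0424, groups overlapping). The erp27 call held in 6 of 12 other settings and in 2 of 8 fits without a single replicate (log2 1.5 to 2.5). dnase1, the RNA helicase gene mov10 and ndufs1 were not well above background in the control and rose at least 3.42-fold, 2.73-fold and 3.14-fold. None of them passed with normexp. Every DMP array had more spots well above background (80.4% to 84.8%) than every DMP control array (74.2% to 79.4%). Whether this difference gave rises out of background was not tested. nectin1l2.2 and the thiamine transporter gene slc19a3.2 were not well above background on any DMP array and fell at least 9.55-fold and 2.8-fold. Further falls were in fgl1l (-2.19), hsf2bp (-1.85), atp13a-like (-1.66), the RNA-binding protein gene zc3h14 (-1.26), the kinase gene sbk2 (-1.25) and wdr53 (-1.23, groups overlapping). The falls in nectin1l2.2, slc19a3.2, fgl1l and sbk2 did not pass with normexp. Over the other settings nectin1l2.2 gave log2 values as weak as -1.31 and slc19a3.2 as weak as -0.65. Their lower bounds therefore hold for the main setting only.

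None of the 26 lists passed with DMP in limma's camera test, where 2 passed an unadjusted p under 0.05, both at adjusted p = 0.442: immune cell (mean 0.53, 95% interval 0.21 to 0.84, 2 of 5 genes higher, tyrobp at 1.02 and il2rg at 0.54) and steroid synthesis and sex steroid receptors (2 of 11 genes higher, nr0b1 at 0.57 and nr3c2 at 0.37). Of the phase I metabolism genes cyp2c19 (1.04), ces3.4 (0.93) and por (0.53) rose, 3 of 10, and 1 fell when adjusted over the list alone (mean 0.21, 95% interval 0.11 to 0.32, adjusted p = 0.57). Limma's fry, which does not compare a list with other genes, passed 6 of the 26 lists with DMP. Among them were phase I metabolism (fry adjusted p = 0.000145) and PPAR targets and fatty acid oxidation (fry adjusted p = 0.00285). In the latter list 2 of 15 genes rose and none fell, with a mean of 0.28 (camera adjusted p = 0.57). Neither ar (log2 0.11, adjusted p = 0.681) nor ppara (-0.22, adjusted p = 0.634) passed. The DMP count was 4152 with slide as a fixed block. It was 1684 with normexp, 1296 on the DMP arrays and their controls alone, 5875 with array weights and as low as 1835, without DMP_control replicate 2, when single replicates were left out.

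**Figure D2:**
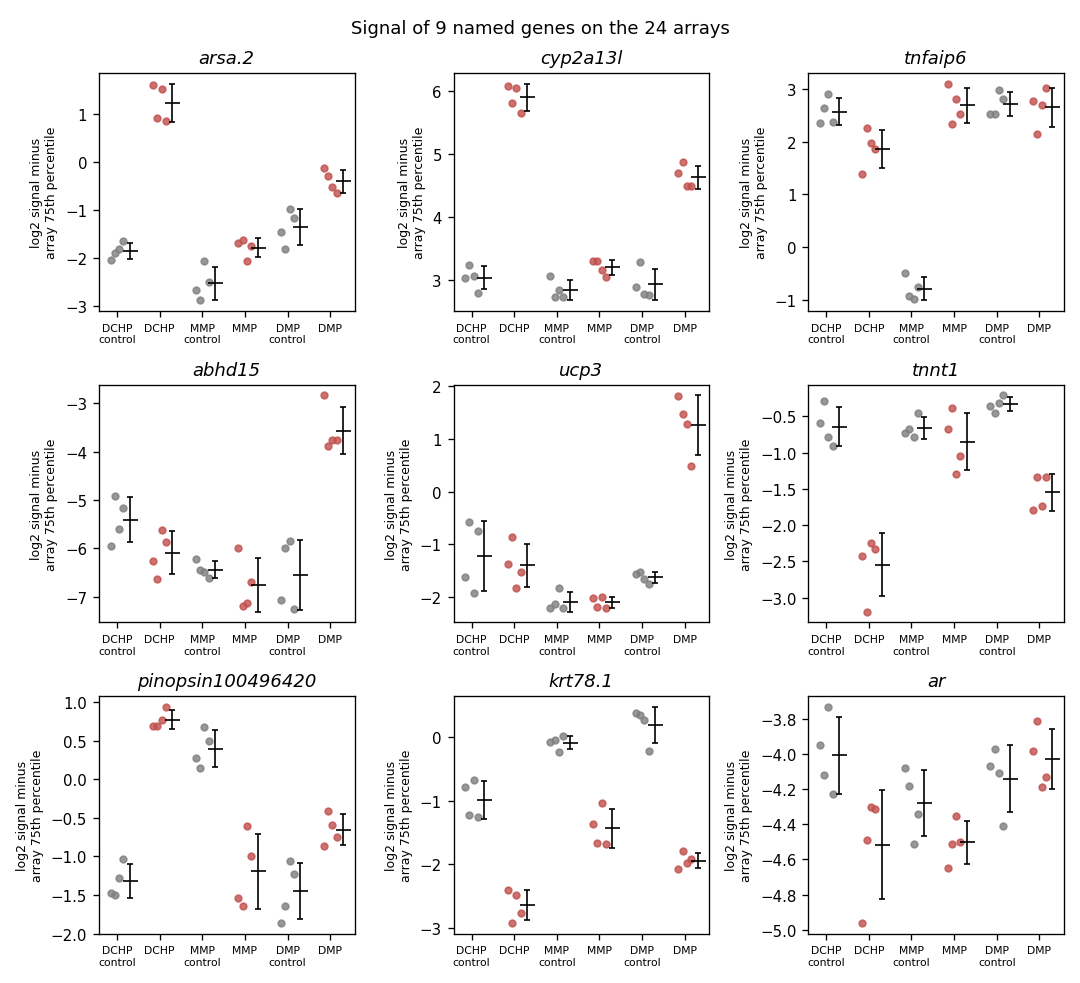
Normalized log2 signal (y axis, relative to the 75th percentile of each array) of 9 named genes on each of the 24 arrays, by group (x axis). Grey points are control arrays, red points are exposed arrays, and the black marks give the mean and SD of each group of 4. For tnfaip6 the MMP control lies at -0.79 while the other control groups lie at 2.57 and 2.71.

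The design also allowed the compounds to be compared with one another, at doses that the labels do not give and that may differ. The diesters DCHP and DMP shared more changed probes than independent lists of those sizes would: 450 were higher with both, where 111.3 would be shared by independent lists, 480 were lower with both, where 117.4 would, and 155 went in opposite directions, where 229.2 would. Their effects correlated across probes with r of 0.344 (Spearman's rho 0.256), and probes are not independent replicates. MMP and DMP, which differ by the second methyl ester, shared 325 higher and 290 lower probes against 84.7 and 80.2, and 97 in opposite directions against 166.2, with r of 0.289 (rho 0.301). DCHP and MMP shared 162 higher and 302 lower probes against 105.3 and 85.6, and 199 in opposite directions against 190.1, with r of 0.048 (rho 0.046). No control arrays were shared between compounds. The comparisons do share one estimate of the spread per probe, so calls can coincide more often than in independent lists even without shared effects. In random splits of the arrays of both compounds, 5 of 100 gave an |r| as large as that of MMP and DMP, 4 of 100 as large as that of DCHP and DMP and 72 of 100 as large as that of DCHP and MMP, the real split included.

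In all 3 comparisons, 94 probes were higher and 129 lower. They include 16 named genes that rose and 15 that fell, listed here after their values had been seen. arsa.2 gave log2 3.08, 0.75 and 0.96 with DCHP, MMP and DMP, and its MMP arrays, at -1.78, lay near DCHP_control (-1.85) and below DMP_control (-1.35), while MMP_control lay lower, at -2.53. The other rises include prorp of mitochondrial RNA processing (1.22, 1.04 and 0.97), mocos, an enzyme of molybdenum cofactor maturation (1.04, 0.54 and 0.43), the lymphatic marker lyve1 (0.62, 0.57 and 0.39) and the AP-1 gene fosb (0.45, 0.42 and 0.49). Besides krt78.1, the falls include sec61b of the protein translocation channel (-1, -0.78 and -0.85), the glutamate receptor gene gria1 (-0.78, -0.53 and -0.54), the transcription factor genes hnf4g (-0.69, -0.46 and -0.53) and snai3 (-0.57, -0.40 and -0.65) and the histamine receptor gene hrh2 (-0.31, -0.36 and -0.57). The krt78.1 falls did not pass a test of their difference: DCHP minus DMP was 0.49 (95% interval 0 to 0.98, adjusted p = 0.26), MMP minus DMP 0.79 (0.30 to 1.28, adjusted p = 0.0626) and DCHP minus MMP -0.30 (-0.79 to 0.20, adjusted p = 0.474).

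**Figure D3:**
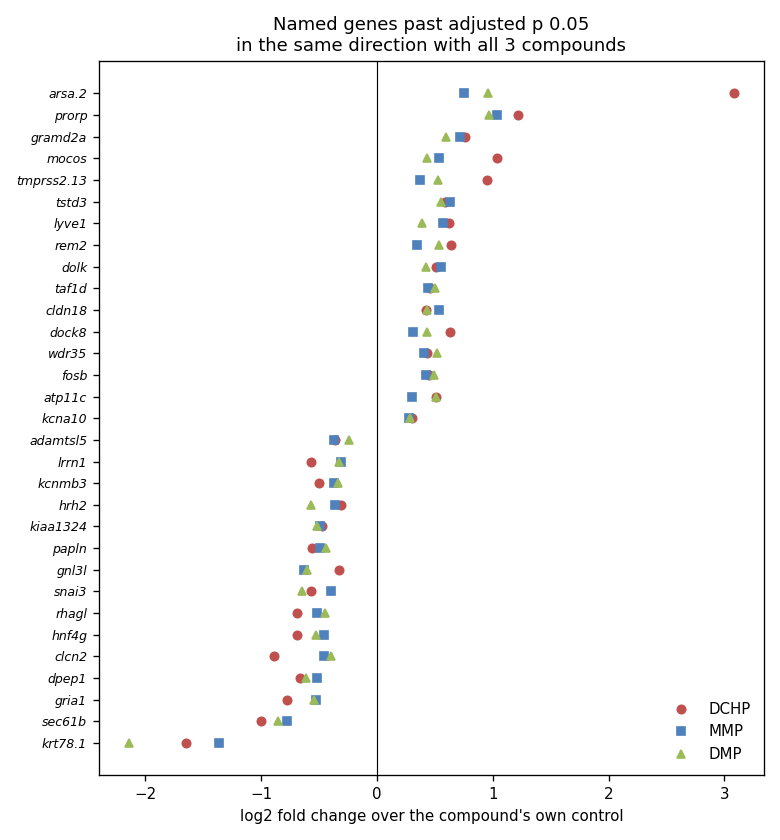
Log2 fold change over the compound's own control (x axis) for the 31 named genes past adjusted p 0.05 in the same direction with DCHP (circles), MMP (squares) and DMP (triangles). arsa.2 stands out with DCHP at 3.08, against 0.75 with MMP and 0.96 with DMP.

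DCHP and DMP, which differ in their alcohol groups, cyclohexyl against methyl, differed in 1689 probes, 969 with a positive difference (DCHP minus DMP) and 720 with a negative one. The P450 probes rose more with DCHP, by 1.16 for cyp2a13l (95% interval 0.77 to 1.55, adjusted p = 0.000578). adm2 rose with DCHP and not with DMP (log2 1.94 and -0.18, difference 2.12, adjusted p = 1.13e-06). The alcohol dehydrogenase gene adh7 moved in opposite directions (1.43 and -1.08, difference 2.50, adjusted p = 5.69e-06), as did prr15 (1.1 and -1.05) and parp14.2, an ADP-ribosyltransferase gene (0.81 and -0.73). vegfd fell with DCHP and gave 0.34 with DMP (difference -1.80). For adh7, prr15 and parp14.2 the controls differed as well: DCHP_control and DMP_control lay at -2.75 and -1.44 for adh7, -1.99 and -1.24 for prr15 and -2.15 and -1.24 for parp14.2. The following did not pass a test of their difference between DCHP and DMP: tnnt1 (-0.69, 95% interval -1.28 to -0.10, adjusted p = 0.173), atp13a-like (-0.21, -0.69 to 0.27), hsf2bp (0.20, -1 to 1.41), ndufs1 (0.18, -0.86 to 1.23) and nectin1l2.2 (0.19, -1.76 to 2.15). For ndufs1 and nectin1l2.2 the folds with both compounds are lower bounds, so these differences cannot show whether the compounds differ. No list passed in limma's camera test: skeletal muscle gave -0.45 (95% interval -0.60 to -0.30, adjusted p = 0.107), phase I metabolism 0.25 (0.10 to 0.40, adjusted p = 0.402), innate immunity 0.23 (-0.01 to 0.47, adjusted p = 0.396) and immune cells 0.12 (-0.33 to 0.57, adjusted p = 0.725). The count was 698 with normexp, 991 on scan day 1 alone, 2535 with slide as a random block and 3521 with array weights.

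MMP and DMP, the monoester and the diester of phthalic acid with methanol, differed in 1223 probes, 523 with a positive difference (MMP minus DMP) and 700 with a negative one. ucp3 rose with DMP and not with MMP (2.89 and -0.01, difference -2.90, adjusted p = 0.000171), and rbm48, one of the P450-tracking probes, rose with DMP by 1.74 and gave 0.36 with MMP (difference -1.38, adjusted p = 0.000205). tnfaip6 (difference 3.53), pinopsin100496420 (-2.38) and ndufs4 of complex I (2.34) also differed, and in each the MMP control lay apart from the DMP control: at -0.79 and 2.71, 0.40 and -1.45, and -1.09 and 0.47. The other probe of ndufs4 gave 0.10. No list passed in limma's camera test, the smallest camera adjusted p being 0.0623 for innate immunity (-0.30, 95% interval -0.54 to -0.07). The receptor gene ar gave a difference of -0.34 (95% interval -0.77 to 0.09) and ppara 0.38 (-0.34 to 1.11). The count was 465 with normexp, 2263 with slide as a fixed block and 2345 as a random block.

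DCHP and MMP differed in 2890 probes, 1547 with a positive difference (DCHP minus MMP) and 1343 with a negative one. cyp2a13l, cyp2f1 and rbm48 rose with DCHP and gave 0.36, 0.38 and 0.36 with MMP, differences of 2.50, 2.43 and 2.47 (adjusted p = 2.2e-08, 2.58e-08 and 2.2e-08). pinopsin100496420 rose with DCHP and fell with MMP (2.09 and -1.59, difference 3.68, 95% interval 3.09 to 4.28), where DCHP_control and MMP_control lay at -1.32 and 0.40. tnfaip6 differed by -4.18. Innate immunity (difference of the means 0.54, 95% interval 0.30 to 0.77, adjusted p = 0.00023), phase I metabolism (0.42, 0.27 to 0.57, adjusted p = 0.0372), liver (0.24, 0.10 to 0.39, adjusted p = 0.0372) and immune cells (0.63, 0.18 to 1.08, adjusted p = 0.0372) were higher with DCHP relative to MMP, and skeletal muscle was lower (-0.63, -0.79 to -0.48, adjusted p = 0.0454). With an estimated correlation innate immunity passed (adjusted p = 0.041), and the others did not, with adjusted p = 0.0807, 0.258, 0.258 and 0.123 for phase I metabolism, liver, immune cells and skeletal muscle. With slide as a fixed block skeletal muscle (-0.61, adjusted p = 0.159) and immune cells (0.56, adjusted p = 0.0772) did not pass, and the other 3 did. With normexp the means were 0.29 for innate immunity, 0.25 for phase I metabolism, 0.25 for liver and -0.39 for skeletal muscle, all of which passed, and 0.35 for immune cells, which did not (adjusted p = 0.152). Without single replicates skeletal muscle passed in 6 of 16 fits, immune cells in 9 and liver in 11. With the stricter filter on dim probes phase I metabolism did not pass in camera (mean 0.17, adjusted p = 0.343). On scan day 2 alone, which holds a single MMP array, the liver mean was 0.10. Of the 10 liver genes, plg, which encodes plasminogen, passed (0.75, adjusted p = 0.0105; 3 genes passed when adjusted over the list alone), and of the muscle genes tnnt1 (-1.71) and klhl31 (-1.28) did. The count was 1010 with normexp, 2 on scan day 2 alone, 4550 with slide as a random block and 5705 with array weights.

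**Figure D4:**
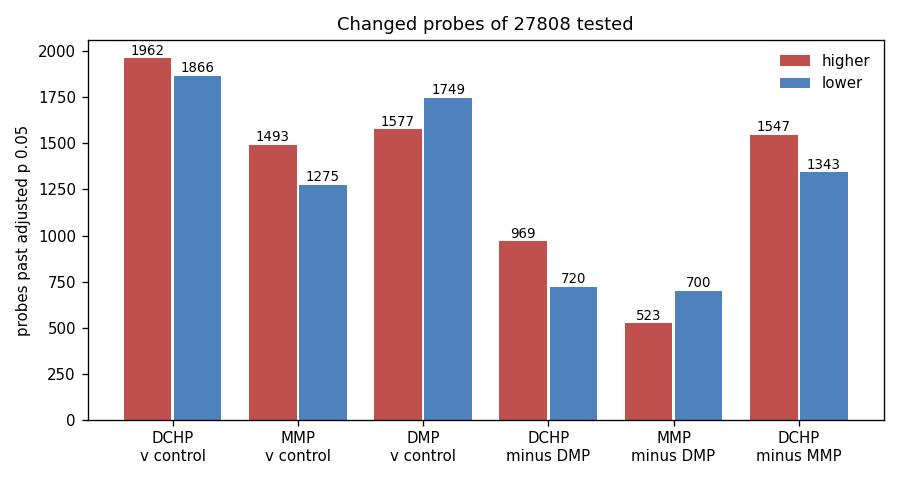
Number of probes past adjusted p 0.05 of 27808 tested (y axis), higher (red) and lower (blue), for each compound against its own control and for each difference between effects of compounds (x axis). The DCHP bars are the highest of the 3 comparisons with control, at 1962 and 1866.

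The control groups differed from one another as well. Between DCHP_control and MMP_control 1120 probes passed adjusted p 0.05, between DCHP_control and DMP_control 238, and between MMP_control and DMP_control 163. Of these, 200, 35 and 71 differed at least 2-fold. An effect of a phthalate therefore cannot be told apart from a difference in origin between its group and its control group.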

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

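The splits of the arrays were planned, while the tests of the 3 patterns below were chosen after the results had been seen.

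Random splits of the same arrays gave, with the real split counted, 1 of 35 with as many changed probes for DCHP (the highest other split had 1), 1 of 35 for MMP (highest other 5) and 1 of 35 for DMP (highest other 863). For the lists passing with DCHP it was 2 of 35 (highest other 4), so chance was not excluded for their number. For differences between compounds it was 1 of 100 for DCHP minus DMP (highest other 1203), 3 of 100 for MMP minus DMP (highest other 1700), 1 of 100 for DCHP minus MMP (highest other 913; those 3 draws kept the real split of a compound, and the highest without one were 72, 1419 and 10) and 2 of 100 for the lists of DCHP minus MMP (highest other 5). Each of these draws split the arrays of all 3 compounds, so it stands for no effect of any compound, not for equal effects. The draws therefore cannot decide whether the effects of 2 compounds differ. For the correlations of effects the splits as large were 4 of 100 for DCHP and DMP (highest other 0.421), 5 of 100 for MMP and DMP (highest other 0.387) and 72 of 100 for DCHP and MMP (highest other 0.357), so chance was not excluded for the last 2.

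In 31 probes, a group was read on 4 of 4 arrays and another on none, over 8-fold apart. Of these, 18 separated a treated group from its own control, 1 of them with a gene symbol (nectin1l2.2, with DMP), and 7 of the 18 also separated control groups from one another, which argues against a response to the phthalate alone for those 7. In 10 of the 31, every group was read on 0 or 4 arrays, as different parents of the groups could give, but the labels name no parents and this cannot be told. When probes were chosen by the same rule without one of the 9 slide pairs, 94 of 108 such choices (a probe can recur) differed in the same direction on the slide left out, all of them for 7 pairs but 16 of 24 with MMP on slide 1 and 60.0% of 15 with DMP on slide 5. With DCHP it was all 11, 11 and 12 on slides 1, 2 and 5, which argues against slide or scan day for the DCHP choices. For MMP and DMP, and so for the pattern as a whole, slide or scan day stays open. Earlier rules on the 18 probes themselves (more than 9 of them over 8-fold apart on each shared slide, which 9 were, then those 9 alone, then the direction in all 18) were dropped after their values were seen, the last 2 because the choice of the probes fixed the outcome.

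The probes of cyp2a13l, cyp2f1 and rbm48 rose together with DCHP and DMP. The largest SD of the log2 difference between any of the 3 was 0.065 over the 24 arrays, against 0.062 between spots of one probe, so they likely read one transcript. Of 19701 pairs among 199 bright genes 78 correlated as highly, and none of 4950 pairs with both probes of the specific class did. cyp2c19, read by a specific probe, correlated with them at r of at most 0.791.

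The mean of the skeletal muscle list was lower with DCHP. A smaller share of muscle RNA would lower all members alike if all were read from the same muscle cells alone. The members changed unequally (an approximate, not an exact, chi-square test gave p = 1.65e-19), which argues against that case only. Loss of one fibre type, or members read in part from other tissue, could give unequal changes. The shifts within the 3 shared slides averaged -0.55 (standard error 0.036), the weakest being -0.48, which argues against slide or scan day as the whole cause. With slide as a fixed block the mean went from -0.53 (standard error 0.052) to -0.52 (0.059) and adjusted p from 0.0183 to 0.0556, so the call ended with 5 fewer degrees of freedom and a wider spread, and an earlier rule that also required the call was dropped after this was seen. No test separated loss of muscle from lower transcription in muscle.

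A sample stood far from the other 3 of its group in 10 of the 180 groups of 4 values looked at, where chance gives about 1 in 20. The gap to the nearest sample, as a share of the group's range, is given for each. The percent of spots well above background stood apart in DCHP replicate 9 (70.7 against 77.1 to 77.5, ratio 0.941) and in MMP_control replicate 6 (69.3 against 72.6 to 73, ratio 0.892). krt78.2 stood apart in DCHP replicate 12 (-6.12 against -6.99 to -6.88, ratio 0.873) and c5 in DCHP replicate 5 (1.22 against 0.78 to 0.84, ratio 0.866). MMP_control replicate 6 stood apart in pxdn (-2.11 against -3.34 to -3.14, ratio 0.839) and ppara (-2.62 against -3.87 to -3.75, ratio 0.902). abhd15 stood apart in DMP replicate 11 (-2.84 against -3.89 to -3.76, ratio 0.873), and DMP_control replicate 6 did in mov10 (-6.28 against -7.41 to -7.22, ratio 0.831) and rbm48 (3.36 against 2.79 to 2.88, ratio 0.843). The mean of the skeletal muscle list stood apart in DCHP_control replicate 3 (0.13 against 0.20 to 0.21, ratio 0.884).

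Effects differed between compounds in 1689 probes for DCHP minus DMP, 1223 for MMP minus DMP and 2890 for DCHP minus MMP. Between DCHP and MMP the lists of phase I metabolism (adjusted p = 0.0372), innate immunity and complement (0.00023), liver (0.0372), skeletal muscle (0.0454) and immune cells (0.0372) differed in limma's camera test. Of these, phase I metabolism (adjusted p = 0.0807 with an estimated correlation), liver (0.258), immune cells (0.258) and skeletal muscle (0.123) lost the call with an estimated correlation. The log2 differences of DCHP minus DMP were 2.12 for adm2, 1.55 for parp14.2, 2.14 for prr15, 2.5 for adh7 and -1.8 for vegfd. Those of MMP minus DMP were 3.53 for tnfaip6, 2.34 for ndufs4, -2.38 for pinopsin100496420, -2.9 for ucp3 and -1.38 for rbm48. Those of DCHP minus MMP were -4.18 for tnfaip6, 2.5 for cyp2a13l, 2.47 for rbm48, 2.43 for cyp2f1 and 3.68 for pinopsin100496420.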

How the results depend on the processing

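The settings by scan day and without cross-hybridizing probes, and the repair of normexp, were chosen after the results had been seen. Of 95 results for named genes, 89 kept their direction under every setting that gave a value and with every replicate left out. Under the same settings and fits, 30 kept their side of the threshold. A result that never passed counts among the 30 even where its direction turned. ppara with DCHP did so (log2 -0.12 to 0.18 over the other settings). The stricter filter gave a value for 59 of the 95 and none for the other 36. Of the probe counts, 60 stayed within 1.5 times, 17 were higher and 16 lower. No paired analysis was possible because a treated group and its own control share at most 1 replicate number, while arrays of one slide were compared within slides and with slide as a block. No DMP array was scanned on day 2, so that day gave no value for DMP. The cause of the changes below was not tested, except that scan days and own arrays leave fewer samples. The share of spots well above background, from 67.1%, limits what can be read of dim probes.

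Changed probes were 3828 with DCHP, 2768 with MMP and 3326 with DMP, and 1689, 1223 and 2890 for DCHP minus DMP, MMP minus DMP and DCHP minus MMP. In the same order, normexp gave 1792, 706, 1684, 698, 465 and 1010 (67.6% higher in place of 53.5% for the last). The compared arrays alone gave 2540, 1520 and 1296 for the compounds. Array weights gave 6172 with MMP, 5875 with DMP and 3521, 2153 and 5705 for the differences. Slide as a random block gave 4431 with MMP and 2535, 2345 and 4550 for the differences, and slide as a fixed block 2263 for MMP minus DMP. Scan day 1 alone gave 1953 with DCHP (63.5% higher in place of 51.3%) and 991 for DCHP minus DMP. Scan day 2 alone gave 114 with DCHP (78.9% higher), 2 with MMP and 2 for DCHP minus MMP. Unadjusted p with a fold minimum gave 2235 with DCHP, 2069 with DMP, 2593 for DCHP minus DMP and 2146 for MMP minus DMP. The looser adjusted p gave 4632 with MMP, 5006 with DMP and 2559, 2019 and 4608 for the differences. With single replicates left out, counts were 2843 to 3523 with DCHP, 936 to 3674 with MMP and 1835 to 4591 with DMP.

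With DCHP, the mean of phase I metabolism was 0.46 and became 0.20 with the stricter filter (adjusted p = 0.128), 0.19 with normexp (0.0126) and 0.39 within slide 2. Innate immunity, 0.40, became 0.08 with normexp (adjusted p = 0.145), 0.22 with the stricter filter (0.0796) and 0.26 within slide 5, and stayed 0.40 with an estimated correlation (0.0663). Skeletal muscle, -0.53, was -0.42 with normexp (0.03), -0.52 with slide as a fixed block (0.0556), -0.54 on scan day 2 (0.0653), -0.53 with an estimated correlation (0.0663) and -0.60 within slide 1. Immune cells, 0.65, were 0.24 with normexp (0.222), 0.59 with slide as a fixed block (0.0556), 0.60 with array weights (0.0821), 0.60 with the authors' matrix (0.0571), 0.48 on scan day 2 (0.0647), 0.65 with an estimated correlation (0.302), 0.16 within slide 1 and 0.59 to 0.76 with single replicates left out.

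For DCHP minus MMP, phase I metabolism, 0.42, was 0.17 with the stricter filter (adjusted p = 0.343), 0.25 with normexp (0.0302), 0.45 on scan day 1 (0.0716) and 0.42 with an estimated correlation (0.0807). Innate immunity, 0.54, was 0.29 with normexp (0.0107). Liver, 0.24, was 0.24 with quantile normalization (0.0994), the authors' matrix (0.106), scan day as a block (0.0548) and an estimated correlation (0.258), 0.25 with slide as a random block (0.0617), 0.10 on scan day 2 (0.584), 0.38 without cross-hybridizing probes (0.0526) and 0.21 to 0.28 with replicates left out, passing in 11 of 16. Skeletal muscle, -0.63, was -0.63 with the stricter filter (0.0886), scan day as a block (0.074), an estimated correlation (0.123) and without cross-hybridizing probes (0.0832), -0.39 with normexp (0.031), -0.61 with slide as a fixed block (0.159), -0.62 as a random block (0.0732), -0.60 with array weights (0.143), -0.54 on scan day 1 (0.252) and -0.68 to -0.59 with replicates left out, passing in 6 of 16. Immune cells, 0.63, were 0.35 with normexp (0.152), 0.56 with slide as a fixed block (0.0772), 0.59 as a random block (0.0617), 0.51 with array weights (0.154), 0.60 with scan day as a block (0.0548), 0.60 on scan day 1 (0.206), 0.63 with an estimated correlation (0.258) and 0.55 to 0.77 with replicates left out, passing in 9 of 16. Limma's fry, which does not compare a list with other genes, passed 10, 0 and 6 of 26 lists with DCHP, MMP and DMP, where camera passed 4, 0 and 0, and 3, 7 and 9 for DCHP minus DMP, MMP minus DMP and DCHP minus MMP, where camera passed 0, 0 and 5. Normexp also gave a correlation of 0.473 between DCHP and DMP in place of 0.344, and turned ces3.4 with DCHP to -0.01 and wdr60 with MMP to -0.03.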

Other observations

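The genes and groups in this part were chosen after their values had been seen. MMP raised 4 of 12 genes of cholesterol and fatty acid synthesis: sqle (log2 0.88), fdft1 (0.71) and sc5d (0.59), enzymes of the sterol pathway, and ldlr (0.37), the receptor that takes up lipoprotein cholesterol. The list did not pass in limma's camera test (adjusted p = 0.426).

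The endoplasmic reticulum chaperone gene hspa5 rose with MMP (log2 0.70) and fell with DMP (-0.65), a difference of 1.35 (limma adjusted p = 0.000589), with the controls of MMP and DMP at 3.14 and 3.05. hsp90b1 (-0.64), pdia4 (-0.58) and creld2 (-0.55) fell with DMP and did not pass with MMP (0.24, 0.18 and 0.38), and their differences of MMP minus DMP were 0.88, 0.76 and 0.93. The collagen chaperone gene serpinh1 rose with MMP (1.26; difference 1.91). The small heat shock genes hsp30e (1.13) and hsp30c (0.62) rose with DMP. The list of heat shock and protein folding did not pass for MMP minus DMP in limma's camera test (adjusted p = 0.114).

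The 25 gamma crystallin genes, of the lens, 20 of them read by cross-hybridizing probes, had group means of 3.85 ± 1.22 in DCHP (2.02 to 4.60 over the arrays), 4.1 ± 0.98 in DCHP_control (2.69 to 4.93), 4.47 ± 0.90 in MMP (3.11 to 4.97), 4.74 ± 0.07 in MMP_control, 4.73 ± 0.12 in DMP and 4.85 ± 0.27 in DMP_control (SD, n = 4). None of the 25 passed in any of the 3 comparisons.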
